A study of Mus musculus with 2 samples.

How the data were processed

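Libraries of the 10x 3' v3.1 chemistry were sequenced on an MGI2000 instrument, 1 from control-treated and 1 from JQ1-treated mice. The deposited matrices hold raw UMI counts for 31053 genes and the same genes in both libraries. The submitters' processing notes name Cell Ranger 3.1.0, Seurat 4.0.0 and the mm10 build; the annotation release and any filter on barcodes are not given in the sources used here. In each library the lowest barcode total was 500 UMIs, and 40 barcodes occurred in both libraries.

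Cells were kept with at least 200 genes and under 20% mitochondrial UMIs; 1481 control barcodes (15.2%) and 1056 JQ1 barcodes (6.51%) were at or over the mitochondrial limit. Doublets were called per library with Scrublet in scanpy 1.11.5, which removed 119 control (1.44%) and 479 JQ1 barcodes (3.31%). Both libraries were clustered together on 2000 variable genes and 30 principal components with 15 neighbours and the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0), with seed 0 and no batch correction. Other computing used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

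Clusters were named from marker lists fixed before the data were examined, requiring at least 3 markers at 2-fold in at least 10% of cells. The naming rule had 4 versions. The version fixed in advance left large keratinocyte and fibroblast clusters unnamed, so that the fold was then taken against the median over clusters, and the version used also left unnamed any cluster led by salivary gland genes or without an own marker among its 10 leading genes. These changes were made after the leading genes of the clusters were seen. A last change, fitted to a single epithelial cluster led by Ly6d and Cyp2f2, was taken back before any list or gene value was read. The doublet caller was changed from approximate to exact neighbours, so that a repeat is identical, after the clusters and T cell sub-clusters were seen; this changed the CD8 sub-cluster counts. Names are by resemblance ("T-like"), and T cells were clustered again alone at resolution 1.0.

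With 1 library per group, cells are not replicates, no test or p-value was made, and changed genes were not counted over a class. Shares have exact Clopper-Pearson intervals at 95% and differences, JQ1 minus control in percentage points, have Newcombe intervals. For genes, UMIs were summed per class and library and scaled to CPM over all genes of the class, with exact Poisson intervals and an exact conditional interval for the ratio. A count of 0 was set to 3 counts. List members counted as measured with at least 20 UMIs over both libraries and 10 CPM in the higher. They counted as higher or lower at 1.5-fold or more if the ratio's exact interval also excluded 1. These counts thus depend on depth as well as on size. List medians have intervals from Poisson redraws and a percentile among 10000 random lists of like expression.

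Genes were named by a rule fixed before the data were examined. In each class with at least 100 cells in both libraries, genes were ranked by the bound of the ratio's interval nearest to 1, with at least 50 CPM, 50 UMIs, a UMI in 5% of cells and 0.5 times the library-wide CPM. Members of the fixed lists were also named; mitochondrial, ribosomal, haemoglobin, sex-linked, receptor-segment and predicted genes were left out of the ranking. Shares of T cells with a CD8 UMI were counted after thinning each cell to 1000 UMIs, which left out 40 control and 46 JQ1 T cells with fewer.

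The ratio table was tested on class sums simulated as Poisson counts, with changed genes set in. The intervals assume the same model, so their coverage was largely fixed in advance, and added spread between cells was not simulated. Intervals held the true ratio for 95.3% of epithelial, 96.2% of T cell, 96.2% of macrophage and 95.9% of neutrophil genes. At 2-fold, the interval lay on the right side of 1 for 100% of changed genes in epithelial cells, 92% in T cells, 94% in macrophages and 94% in neutrophils, and at 1.5-fold for 100%, 68%, 64% and 76%. Alternatives changed the cell filter, doublet removal, resolution, joint clustering, scaling, summing, member filter and free-RNA filter one at a time. The alternative without a cell filter dropped the gene and mitochondrial limits alone and still removed doublet calls, although it was worded in advance as keeping every barcode. Further alternatives, added after the data were seen, kept every barcode with doublet calls, changed the share's denominator, left out the Elane cluster, clustered immune cells alone, left 14776 genes that free RNA could have brought out of T cell clustering, split the epithelial clusters and changed the set of CD8 cells.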

Results

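RNA of single cells was measured in squamous tumours of the tongue, a model of head and neck cancer, in C57BL/6 mice given the carcinogen 4NQO. The mice were then treated for 10 days with JQ1, an inhibitor of BET bromodomains, or with control. The labels give 1 library per treatment, so no value below has a replicate and none carries a test. The number of mice behind each library is not given in the sources used here. The control library held 9754 barcodes with 118382532 UMIs, and the JQ1 library held 16233 barcodes with 99565417 UMIs. After filtering, 8150 control cells (median 11302.5 UMIs) and 13989 JQ1 cells (median 3869 UMIs) were kept. Intervals are 95% intervals and cover counting error only, not differences between mice, tumours or preparations.

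The title of the series names immune cells within the tumours, and the comparison of cell classes asks how their shares differed under JQ1. Epithelial-like cells were the largest class of the control library at 61.9% of kept cells (60.8 to 62.9), against 10.3% (9.79 to 10.8) in the JQ1 library. Stromal classes made up more of the JQ1 library: fibroblast-like cells were 10.8% in control and 34.0% in JQ1, endothelial-like cells 6.47% and 16.3%, and pericyte or smooth muscle-like cells 2.09% and 5.77%. Outside the keratin-rich clusters the endothelial difference was -0.146 points (-1.74 to 1.38), the pericyte difference 0.536 (-0.474 to 1.45), and the fibroblast difference 7.30 (5.40 to 9.16). Schwann-like cells, which ensheath nerves, were 0.454% of control and 7.91% of JQ1 cells. Clusters led by salivary gland genes such as Muc5b, a secreted mucin, held 2.53% of control and 10.99% of JQ1 cells. Haemoglobin-rich erythroid-like cells numbered 264 in JQ1 (1.89%) and 0 of 8150 in control, which allows a control share of up to 0.0368%. A further unnamed cluster rich in keratins held 223 control and 4 JQ1 cells.

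**Figure D1:**
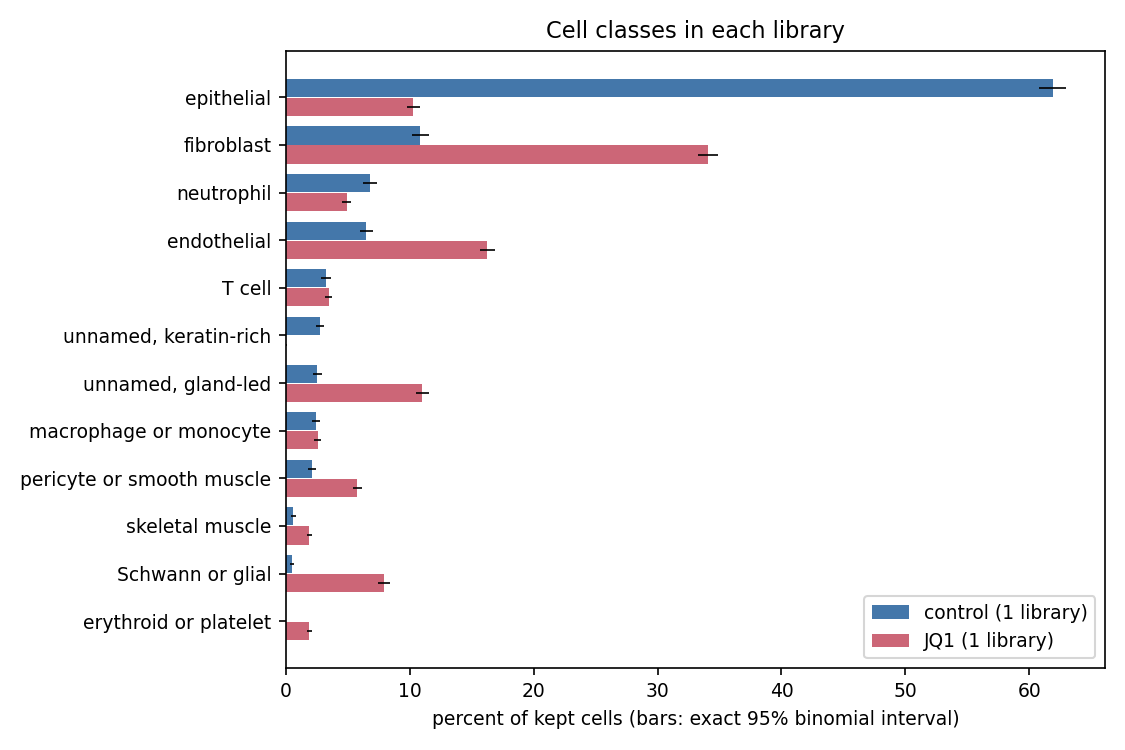
Share of kept cells in each class, in percent, for the control and the JQ1 library (1 library each), with exact 95% intervals that cover counting error only. Epithelial-like cells were 61.9% of the control and 10.3% of the JQ1 library.

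Immune cells made up a similar part of both libraries, and several differences in shares depended on the cell filter. They were 12.4% (11.7 to 13.1) of control and 10.9% (10.4 to 11.4) of JQ1 cells, a difference of -1.49 percentage points (-2.38 to -0.614). Of the immune cells, T-like cells were 26.0% (23.3 to 28.8) in control and 31.6% (29.2 to 34.0) in JQ1. The macrophage or monocyte-like class, which also held dendritic cells, was 19.5% (17.1 to 22.1) and 23.4% (21.3 to 25.7); when immune cells were clustered alone, macrophages were 7.52% and 11.7% and dendritic cells 9.59% and 7.40%. Neutrophil-like cells were 54.5% (51.4 to 57.6) and 45.0% (42.5 to 47.5), a difference of -9.51 points (-13.4 to -5.54). With the stricter cell filter the differences were -0.115 points (-1.01 to 0.764) for immune cells, 1.46 (-1.74 to 4.52) for macrophages and -4.24 (-8.62 to 0.150) for neutrophils, with 0 inside each interval. Dendritic cells had a class of their own under that filter, so its macrophage difference is for an unlike class. The T cell difference was 5.55 (1.95 to 9.08), against 4.23 (0.121 to 8.25) with that filter and 5.03 (1.48 to 8.51) with none. With no filter the immune difference was -0.585 (-1.37 to 0.183). One neutrophil cluster, led by the granule genes Camp, Ngp and Elane of developing neutrophils, held 5 of 551 control and 160 of 687 JQ1 neutrophils. Without that cluster the neutrophil difference was -15.7 points and the T cell difference 9.12 points, and with each library clustered alone they were -22.9 and 0.620 points. The immune share depended on its denominator and on the clustering: outside the keratin-rich clusters it was 35.1% in control and 12.2% in JQ1, and with each library clustered alone the difference was 0.903 points in the other direction. In that last clustering no control cluster took the macrophage name (0 of 8150 cells), so that the control immune share was 9.96% and the shares within it lacked that class.

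**Figure D2:**
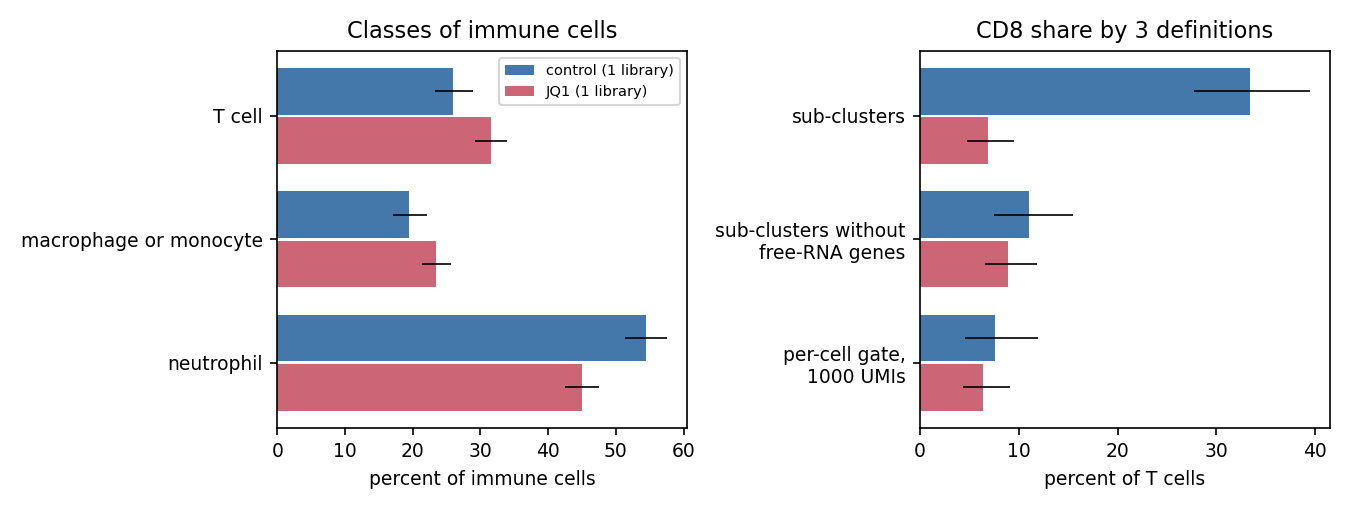
Shares within immune cells, in percent, for the control and the JQ1 library (1 library each), with exact 95% intervals that cover counting error only. Neutrophil-like cells were 54.5% of control and 45.0% of JQ1 immune cells, and T-like cells 26.0% and 31.6%.

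CD8-type T cells were compared because they are the cytotoxic arm of the tumour-infiltrating T cells. Sub-clusters named CD8 held 88 of 263 control T-like cells (33.5%, 27.8 to 39.5) and 33 of 482 JQ1 T-like cells (6.85%, 4.76 to 9.48), a difference of -26.6 points (-32.8 to -20.6), which was -8.16 points under a stricter cell filter. Of those control cells, 72 were in a sub-cluster with 0 of 482 JQ1 T cells, which allows up to 0.622%, so that this sub-cluster cannot be told from its library. Without thinning, 20 of 263 control T-like cells had a Cd8a UMI and 21 a Cd8b1 UMI. Most of the 88 control cells named CD8 therefore had neither, although a missing UMI does not show that the RNA was absent. In JQ1 the counts were 22 and 36 of 482. Clustered without 14776 genes that free RNA could have brought, CD8 sub-clusters held 29 control and 43 JQ1 T cells, a difference of -2.11 points (-7.00 to 2.23). Counted per cell at an equal depth of 1000 UMIs, cells with a Cd8a or Cd8b1 UMI and no Cd4 UMI were 17 of 223 in control (7.62%, 4.50 to 11.9) and 28 of 436 in JQ1 (6.42%, 4.31 to 9.15). Without thinning the same gate held 9.13% of control and 8.30% of JQ1 T cells. Fibroblasts, which should lack these receptors, passed it in 0 of 298 control cells (up to 1.01%) and 1 of 1702 JQ1 cells (0.0588%). Median depths were 1925 and 2345.5 UMIs in T cells and 2941 and 3808 UMIs in fibroblasts. Regulatory-type sub-clusters, marked by Foxp3, were 15.6% of control and 17.2% of JQ1 T cells, and gamma-delta or Th17-type sub-clusters 22.8% and 19.9%. Without free-RNA genes the regulatory shares were 24.7% and 28.2%. Sub-clusters that took no name held 28.1% of control and 56.0% of JQ1 T cells, a difference of 27.9 points (20.6 to 34.6), and 24.7% and 30.9% without free-RNA genes.

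Among T-like cells, some cytokines of type 17 immunity were lower under JQ1 while the cytotoxic list as a whole sat near 0. Il17f had 963 CPM (888 to 1043) in control and 297 CPM (270 to 327) in JQ1. Il22, a cytokine that acts on epithelium, had 205 and 37.9 CPM, while Il17a, with 2601 and 1812 CPM, stayed within 1.5-fold. Of 9 measured members of the IL-17 list, 3 were lower and 0 higher by at least 1.5-fold, with a median log2 ratio of -0.52 (-0.72 to -0.24). Il2ra, the alpha chain of the IL-2 receptor, was 2.07-fold higher (1.67 to 2.58), and the chemokine receptor Cxcr4 1.92-fold higher (1.67 to 2.22). The cytotoxic list over all T cells had a median of -0.04, with 3 of 21 members higher and 4 lower. Gzma and Gzmf, granule proteases of killer cells, were higher: Gzma had 19.0 CPM in control and 182 CPM in JQ1, and Gzmf had 0 UMIs in control and was at least 41.3-fold higher against 3 counts. Ctsw and Klrd1, expressed by cytotoxic lymphocytes, were 2.29-fold and 2.20-fold lower, Ifitm1 3.38-fold lower, and Ifng had 281 and 252 CPM. Pdcd1, the receptor PD-1, had 261 CPM (222 to 304) in control and 217 CPM (194 to 242) in JQ1. The exhaustion list had a median of 0.13, the regulatory list 0.18, the naive and memory list 0.24, S phase 0.44 and G2 and M phase -0.34. Within the CD8 sub-clusters the cytotoxic median was 0.56 (-0.01 to 0.74), with 7 of 17 members higher and 5 lower, the exhaustion median 0.73 and the naive and memory median -1.34. These medians compare unlike sub-clusters, since 72 of the 88 control cells lay in a sub-cluster with 0 JQ1 cells. Median depths were 1590 UMIs in control and 3738 in JQ1. The markers that name CD8 sub-clusters also include Gzmk, Gzmb, Prf1, Nkg7 and Eomes of the cytotoxic list. CD8-gated cells, taken without thinning, numbered only 24 in control and 40 in JQ1. These numbers, like those of the CD8 sub-clusters, were under the cell limit for naming genes. The gated cytotoxic median was -0.59 (-0.78 to -0.19), the exhaustion median -0.16 (-0.51 to 0.35) and the naive and memory median 0.54 (0.0059 to 1.04). These intervals cover counting error in summed UMIs and not the spread between so few cells. Whether the gated cytotoxic median lies below 0 beyond that spread was not tested. The gated exhaustion interval held 0, as did the cytotoxic interval of the sub-clusters. No difference between gated cells and sub-clusters was tested. The keratin gene Krt15, 9.62-fold higher in JQ1 T cells, is an epithelial gene, and the gland gene Muc5b had 31.6 CPM in control and 554 CPM in JQ1 T cells. The T cells came from a cluster led by Rgs1 and Ctla4 (210 control and 393 JQ1 cells) and a cluster led by Il17a (53 and 89).

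In epithelial cells the comparison asks whether antigen presentation, interferon genes and proliferation differed under JQ1. No step separated tumour from normal epithelium, so the values are for all cells of the epithelial class and not for tumour cells alone. MHC class I genes, which display peptides to CD8 T cells, were higher in the JQ1 library: 9 of 20 measured members were higher and 0 lower by at least 1.5-fold, with a median log2 ratio of 0.51 (0.48 to 0.58). H2-K1 (ENSMUSG00000061232), a class I heavy chain, had 676 CPM (671 to 681) in control and 1439 CPM (1423 to 1456) in JQ1. B2m (ENSMUSG00000060802), the class I light chain, was 1.71-fold higher (1.68 to 1.75), and the peptide transporter Tap1 2.14-fold higher (2.01 to 2.27). Interferon response genes were also higher, 13 of 17 by at least 1.5-fold and 0 lower, with a median of 0.998 (0.85 to 1.18). Irf7 (ENSMUSG00000025498), a transcription factor of the interferon response, was 4.45-fold higher (3.87 to 5.13) and the T-cell chemokine Cxcl9 3.61-fold (3.42 to 3.81), and the ubiquitin-like modifier Isg15 had 6.65 and 25.2 CPM. Both medians lay at percentile 100 among 10000 random lists of like expression, which describes these libraries only. The median over all measured epithelial genes was 0.14, and with size factors that set it near 0 the MHC class I median was 0.37 and the interferon median 0.86. With each library clustered alone the interferon median was 1.82, and with no filter on members 1.53. The epithelial clusters differed between libraries. The Krt15 cluster held 1408 control and 772 JQ1 cells, the Krt13 cluster 932 and 317, and the Krt6b cluster 575 and 117. A Krt42 cluster held 782 and 25, a Krt16 cluster 624 and 74, and a Cyp2f2 cluster, with duct genes among its leading genes, 82 and 134. Without the Cyp2f2 cluster the MHC class I median was 0.547 and the interferon median 0.929. A cluster with Ppbp and Stmn2 among its leading genes held 641 control cells and 0 of 1439 JQ1 epithelial cells, which allows up to 0.208%. Within the Krt15, Krt13 and Krt6b clusters the interferon median was 0.55, 0.58 and 2.23, and the MHC class I median 0.28, 0.31 and 1.18. Of the MHC class I members 4 of 21, 0 of 18 and 18 of 21 were higher by at least 1.5-fold in these clusters. In the Krt13 cluster both medians lay inside the range of random lists, at percentiles 94.1 (MHC class I) and 94.7 (interferon).

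**Figure D3:**
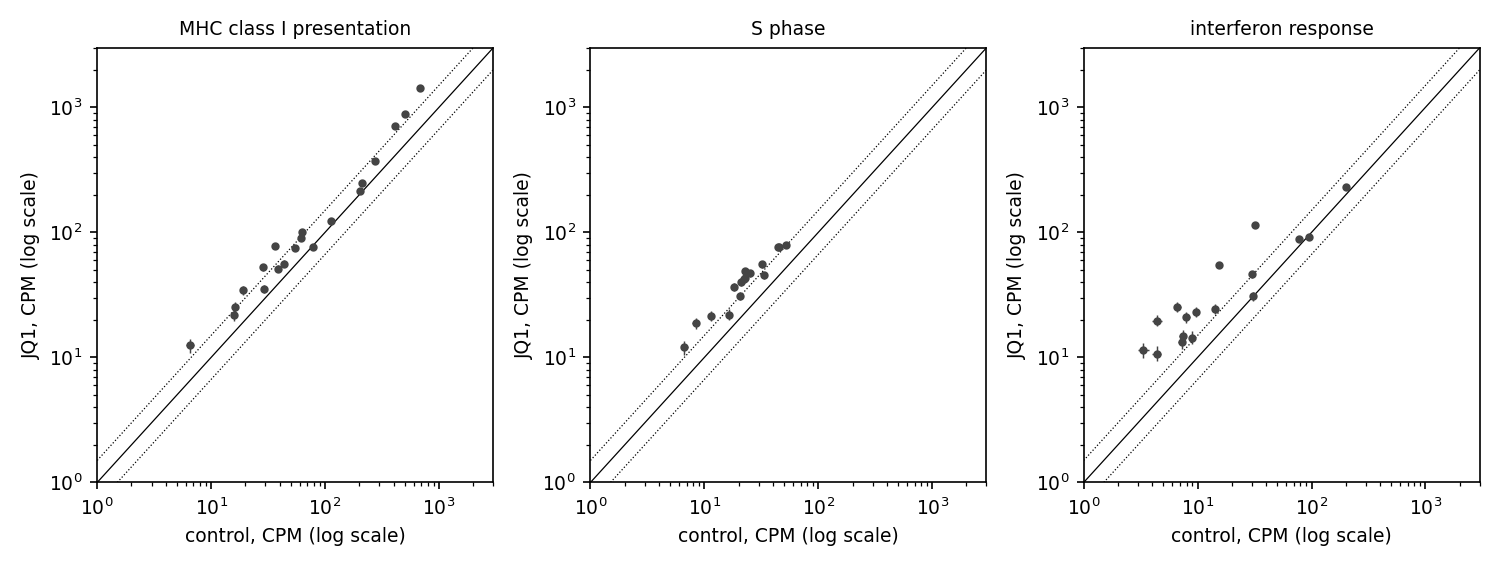
CPM of measured members of the interferon response, MHC class I and S phase lists in epithelial-like cells of the control and the JQ1 library (1 library each). H2-K1 had 676 CPM in control and 1439 in JQ1.

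Over all epithelial clusters together, DNA replication genes were higher in the JQ1 library, though not within the Krt6b cluster. Of 16 measured S phase members 14 were higher and 0 lower by at least 1.5-fold, with a median of 0.88 (0.79 to 0.91). Mcm5, part of the replicative helicase, was 2.14-fold higher (1.98 to 2.31) and Dtl 2.23-fold (1.97 to 2.53). The G2 and M phase list had a median of 0.27 (0.21 to 0.36), with 3 of 18 members higher and 0 lower; Top2a, which untangles chromosomes, had 75.9 and 138 CPM and the proliferation marker Mki67 55.0 and 96.6 CPM. With size factors the G2 and M median was 0.13, and in the Krt6b cluster it was -0.42 and the S phase median -0.18. Hexim1, often raised by BET inhibitors, was 1.86-fold higher (1.74 to 1.98) and Txnip 3.32-fold (3.16 to 3.50), while the whole list of such genes had a median of 0.07 with 3 of 7 members higher. Myc, often lowered by BET inhibitors, had 112 CPM in control and 145 CPM in JQ1, and its list a median of 0.06. Neutrophil chemoattractants and acute cytokines were lower, 5 of 8 members by at least 1.5-fold and 0 higher, with a median of -0.81 (-0.90 to -0.73); Cxcl5 had 94.5 and 16.9 CPM and Il1a was 3.17-fold lower. Wound and stress keratinocyte genes had a median of -0.70 (-0.77 to -0.63), with 5 of 10 members lower; the calprotectin genes S100a8 and S100a9 were 2.21-fold and 3.08-fold lower. The hypoxia and glycolysis list had a median of -0.41 with 6 of 17 members lower, among them Egln3, 2.64-fold, and Ldha, 1.67-fold. Dissociation and immediate early genes, which tissue handling can induce, had a median of 0.53 with 8 of 16 members higher; Fosb was 3.19-fold higher. The genes named by size included Plac8, 12.2-fold higher, and AA467197, 13.5-fold higher, against Stmn2, 45.5-fold lower, Krt42, 30.5-fold lower, and Krt1, a keratin of cornifying cells, 8.99-fold lower. Stmn2 was a leading gene of the cluster with 641 control and 0 JQ1 cells, and Krt42 of the cluster with 782 and 25. These folds may therefore come from the mix of clusters. The S phase, wound and hypoxia medians were also taken over that mix. The squamous differentiation median was 0.06, the basal keratinocyte median -0.02, the partial EMT median -0.09, the p53 target median 0.28 and the stem-cell associated median 0.33. T-cell and monocyte chemokines had a median of 0.13, NF-kB targets 0.12, checkpoint ligands 0.10 and MHC class II genes -0.22.

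**Figure D4:**
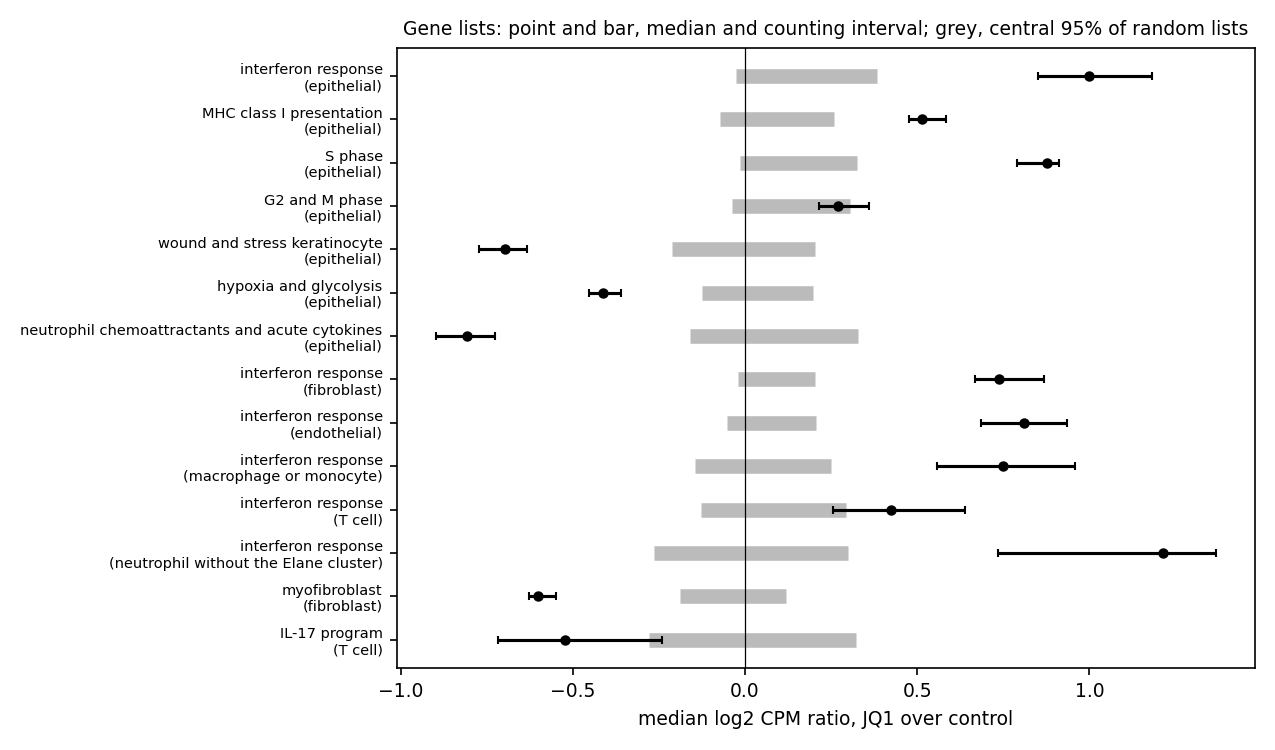
Median log2 ratio of JQ1 over control for a selection of the fixed gene lists and classes (1 library each), with 95% intervals that cover counting error only. Neutrophils are shown without the Elane cluster, and lists left out include genes often raised or lowered by BET inhibitors. In epithelial cells the interferon median was 0.998 and the neutrophil chemoattractant median -0.81.

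The macrophage or monocyte class was compared for interferon genes and activation. Interferon response genes were higher in JQ1, 16 of 33 by at least 1.5-fold and 0 lower, with a median of 0.75 (0.56 to 0.96). Ifnb1, a type I interferon, was 6.06-fold higher (3.96 to 9.71), the antiviral gene Rsad2 4.90-fold (3.36 to 7.39) and Cxcl10 2.14-fold (1.96 to 2.35). Cd274, the checkpoint ligand PD-L1, had 122 CPM (99.9 to 149) in control and 225 CPM (204 to 248) in JQ1. Genes of alternatively activated macrophages had a median of 1.22 (0.94 to 1.40) with 7 of 12 higher and 0 lower, among them Spp1, 3.45-fold, and Il10, 5.49-fold, while the inflammatory list had a median of 0.39. Apoe, a lipid carrier of tissue macrophages, was 4.43-fold higher (4.22 to 4.66) and Lyz2, the myeloid lysozyme, 4.07-fold. MHC class II genes had a median of -0.51 (-0.66 to -0.44), with 4 of 11 members lower and 1 higher; the invariant chain Cd74 was 1.55-fold lower. T-cell and monocyte chemokines had a median of 0.44, NF-kB targets 0.22, checkpoint ligands 0.23, S phase 0.25 and G2 and M phase -0.85. Genes often lowered by BET inhibitors had a median of 0.58 (0.03 to 0.80) with 5 of 11 members higher and 2 lower, and genes often raised by them -0.06. Cd207, the Langerhans cell lectin, was 54.8-fold lower and Cma1, a mast cell protease, 8.42-fold lower. This class was a mixture: clustered alone, the immune cells gave 76 control and 179 JQ1 macrophages, 97 and 113 dendritic cells, 11 and 10 mast cells and 2 and 26 B cells, and a dendritic cluster with Cd207 held 21 control cells and 0 of 1527 JQ1 immune cells, which allows up to 0.196%. In the macrophages of that clustering the interferon median was 0.42 (0.21 to 0.73), with 6 of 28 members higher and 1 lower. The alternative activation median was 0.52 and the MHC class II median -0.40. The median of genes often lowered by BET inhibitors was 0.38 (-0.08 to 0.98) there, with 0 of 9 members higher and 1 lower. The S phase and G2 and M phase medians, over 2 members each, were -0.19 and 0.23. The interferon median of the named class was 0.19 with doublet calls kept and 0.20 with no cell filter. In both settings dendritic cells had a class of their own. The macrophage class then held 96 control and 233 JQ1 cells with doublet calls kept, and 98 and 252 with no cell filter.

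Neutrophils of the JQ1 library carried far more granule transcripts, most of them in the cluster led by Camp, Ngp and Elane. Camp, an antimicrobial granule peptide, had 71.0 CPM in control and 18944 CPM in JQ1, Ngp 599 and 14992 CPM, and Ltf, lactoferrin, was 52.6-fold higher (38.6 to 73.7). The granule list had a median of 1.28 (1.07 to 1.76) with 11 of 12 members higher, and the activation list -1.03 (-1.07 to -0.97) with 10 of 11 lower. The NF-kB list had a median of -0.76 and the hypoxia list -0.56. Without the Elane cluster the granule median was -0.23, the activation median -0.11, the NF-kB median -0.14 and the hypoxia median -0.31. The interferon median was 0.62 (0.26 to 0.88) with that cluster and 1.21 (0.74 to 1.37) without it, where 13 of 26 members were higher and 1 lower and Isg15 was 4.94-fold higher (3.37 to 7.45). Neutrophils of the libraries also parted beyond that cluster: when immune cells were clustered alone, the neutrophil sub-clusters held 7 control and 434 JQ1, 278 and 16, 210 and 9, 0 and 125, 54 and 30, and 1 and 46 cells. These ratios therefore compare largely different neutrophil clusters. Hmox1, haem oxygenase, was 4.54-fold lower with the cluster and 3.59-fold lower without it.

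In fibroblast-like cells myofibroblast genes were lower and interferon genes higher under JQ1. Of 15 myofibroblast members 8 were lower and 0 higher by at least 1.5-fold, with a median of -0.60 (-0.63 to -0.55). The contractile genes Tagln and Acta2 were 5.76-fold and 4.93-fold lower, Cthrc1 5.87-fold and the matrix gene Postn 2.15-fold. The interferon median was 0.74 (0.67 to 0.87) with 22 of 32 members higher and 0 lower, and Cxcl9 was 3.09-fold higher (2.60 to 3.70). Neutrophil chemoattractants had a median of 0.54 (0.23 to 0.89); Cxcl5 was 3.15-fold higher (2.87 to 3.46) and Il11 2.58-fold (2.34 to 2.85). The inflammatory fibroblast median was 0.28, the MHC class I median 0.40, and the medians of genes often lowered or raised by BET inhibitors -0.05 and -0.09. In endothelial-like cells 22 of 34 interferon members were higher and 0 lower, with a median of 0.81 (0.69 to 0.93). Part of these cells came from a cluster led by the lymphatic genes Ccl21a and Mmrn1, which held 47 of 527 control and 505 of 2275 JQ1 endothelial cells. Over the whole class the monocyte chemokines Ccl7 and Ccl2 were 7.28-fold and 2.56-fold higher, and Car4, a capillary carbonic anhydrase, 4.11-fold lower. In pericyte or smooth muscle-like cells the interferon-inducible GTPases Gbp2 and Iigp1 were 3.65-fold and 2.91-fold higher, and Rrad was 2.32-fold lower. In T cells the interferon median was 0.43 (0.25 to 0.64), with 8 of 28 members higher and 2 lower.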

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

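The tests by class shares outside the keratin-rich clusters, by single epithelial clusters, by the dissociation list, by the RNA that free RNA would need to bring, by T cells clustered without free-RNA genes, by every barcode with doublet calls included and by ratios of CD8 shares were chosen after the results were seen, as was the 1.5-fold limit for list medians that go opposite ways. The per-cell CD8 gate was fixed before the data were examined, but what it would show under an explanation was written afterwards.

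Neutrophil chemoattractants and acute cytokines went opposite ways in different cell classes, with no test of the difference. The median log2 ratio was 0.72 (0.41 to 1.09) in macrophage or monocyte-like cells, where Cxcl1 was 3.14-fold and Il1a 3.11-fold higher under JQ1, and 0.39 (0.16 to 0.72) in the macrophages of immune cells clustered alone, with 2 of 9 members higher and 2 lower. It was -0.81 (-0.90 to -0.73) in epithelial cells and -1.03 (-1.11 to -0.99) in neutrophils, and -0.12 in neutrophils without the Elane cluster. Within the Krt15, Krt13 and Krt6b epithelial clusters it was -0.54, -0.41 with 0 of 3 members lower, and -0.78 with 3 of 8 higher and 5 lower. Erythroid-like cells, a class outside the comparisons, were 1.89% of JQ1 cells and none of the control cells; they carried Alas2, the enzyme that starts haem synthesis in red cell precursors, at 1262 CPM. With no gene or mitochondrial limit but doublet calls removed they were 930 of 15754 JQ1 cells (5.90%) and 3 of 9635 control cells, and with the stricter filter 1.05% of JQ1 cells. Clusters led by salivary gland genes, also outside the comparisons, were 10.99% of JQ1 against 2.53% of control cells. The neutrophil cluster led by Camp, Ngp and Elane was 23.3% of JQ1 neutrophils against 0.907% of control neutrophils, with Elane at 1950 CPM and Mpo at 768 CPM in its JQ1 cells.

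The epithelial share was 61.9% in control and 10.3% in JQ1. The cell filter does not account for it, since with every deposited barcode kept, doublet calls included, the difference was -58.8 points (-59.8 to -57.8), and -53.4 (-54.4 to -52.3) with doublet calls removed. A loss of keratinocytes alone would leave the other classes in proportion, yet outside the keratin-rich clusters neutrophils differed by -13.6 points (-15.2 to -12.2) while Schwann-like cells differed by 7.53 points. These 2 classes were picked after the shares were seen. Other classes did stay in proportion: the endothelial difference was -0.146 (-1.74 to 1.38) and the pericyte difference 0.536 (-0.474 to 1.45). More gland, nerve and muscle in the JQ1 piece of tissue stays open as a part of the difference. Gland-led and Schwann-like shares were higher there, but for skeletal muscle the difference was 0.455 points (-0.131 to 0.942). Gland-led, Schwann-like and skeletal muscle cells were 10.99%, 7.91% and 1.90% of JQ1 kept cells, against an epithelial difference of -51.6 points. Such cells alone were therefore too few to account for it. An effect of JQ1 on the tumour and a difference between mice or tissue pieces were not separable with 1 library each.

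The interferon list had a median above 0 in epithelial, fibroblast, endothelial, macrophage and T cells, though in T cells only 8 of 28 members were higher and 2 lower, and in macrophages of immune cells clustered alone 6 of 28 and 1. Different epithelial clusters may not be the whole cause, since the lower of the medians within the Krt15 and Krt13 clusters was 0.55 (0.31 to 0.70). It lay below the 0.998 over all epithelial cells, so that part of that value may come from the mix of clusters. The Krt13 cluster adds no weight, since its interferon median lay inside the range of random lists. Over all measured genes the median was 0.12 in the Krt15 and 0.20 in the Krt13 cluster. A different mix of cells within a cluster was not tested. Free RNA from other cells stays open in epithelial cells: it would need to bring a median of 21.0% of the library-wide level of 17 members (lower quartile 9.53%), against 46.5% held of macrophage markers and 7.81% of the next class, but epithelial cells held up to 173% of a macrophage marker and so express some of these themselves; the rule that this leaves the test undecided was set after its outcome was seen. Dissociation stress was argued against in fibroblasts, where its list had a median of -0.12 (-0.14 to -0.09), and in the Krt6b epithelial cluster, at -0.68 (-0.73 to -0.62); in the Krt15 and Krt13 clusters both lists were higher, the lower dissociation median being 0.14, as in endothelial and macrophage cells, the lower being 0.34 (0.31 to 0.37), and it stays open in these. The treatment and a difference between mice also stay open and were not tested.

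The CD8 sub-cluster share was 33.5% in control and 6.85% in JQ1, but 30.1% and 1.36% with doublet calls kept, 25.5% and 17.4% with the stricter cell filter and 38.4% and 19.8% with no filter. A lower number of CD8 T cells by the ratio of the first pair, 0.205 (0.141 to 0.296), was argued against by the per-cell gate at equal depth, where the ratio was 0.842 (0.471 to 1.51), if CD8 UMIs are detected alike per cell in both libraries; smaller differences, as with the stricter filter, are not excluded. Free RNA splitting the sub-clusters by library stays open: without 14776 genes the ratio was 0.809 (0.518 to 1.26), but the control share was then 29 of 263 cells, so that a loss of the CD8 call cannot be told apart from free RNA.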

How the results depend on the processing

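Alternatives named as added were chosen after the data were seen: the denominator, the Elane cluster, immune cells alone, free-RNA genes, single epithelial clusters, the keratin-rich cluster and the other sets of CD8 cells. Removing the cell filter left doublet calls out, and an added alternative kept both. Unless a construction shows it, the cause was not tested. Shares are differences in percentage points and lists are median log2 ratios.

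The immune share difference was -0.115 with the stricter cell filter, -0.585 with no filter, -0.366 with no filter and doublets kept, 0.903 (reversed) with each library clustered alone, -22.9 without keratin-rich clusters in the denominator and -2.47 without the Elane cluster. The T cell share difference was 0.620 with libraries clustered alone and 9.12 without the Elane cluster. The CD8 share difference was -8.16 (stricter filter), -18.6 (no filter), -12.9 (no filter, doublets kept), -28.8 (doublets kept), -4.37 (clustered alone), -1.20 (per-cell gate) and -2.11 (no free-RNA genes). The macrophage share difference was 1.46 (stricter filter, -1.74 to 4.52), 6.34 (no filter), 6.61 (no Elane cluster) and 22.2 with libraries clustered alone, since no control cluster then took that name. Dendritic cells had a class of their own with the stricter filter and with no filter, but not in the main setting. The macrophage classes of these settings are therefore unlike. The neutrophil share difference was -4.24 (stricter filter), -22.9 (clustered alone) and -15.7 (no Elane cluster).

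In epithelial cells the MHC class I median was 0.71 with no cell filter, 0.60 with doublets kept besides, 0.45 at resolution 0.5, 0.62 at resolution 2, 0.68 with libraries alone, 0.37 with size factors, 0.38 as a mean over cells, 0.59 with no member filter, 0.28, 0.31 and 1.18 in the Krt15, Krt13 and Krt6b clusters, and 0.59 with the unnamed keratin-rich cluster. The interferon median was 0.84 with no cell filter, 0.78 with doublets kept, 0.81 at resolution 0.5, 1.82 with libraries alone, 0.74 as a mean over cells, 1.53 with no member filter, 1.39 with the free-RNA filter, and 0.55, 0.58 and 2.23 in those clusters. The G2 and M phase median was 0.20 with no cell filter, 0.37 at resolution 2, 0.13 with size factors, 0.38 in the Krt13 cluster and -0.42 (reversed) in the Krt6b cluster.

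The cytotoxic median in CD8 cells was -0.0083 with the stricter filter, 0.12 with no filter, 0.0301 with doublets kept, 0.08 at resolution 2, -0.10 with libraries alone, 0.28 with no member filter, 0.18 in CD8 cells without free-RNA genes, -0.59 in gated cells and -0.0423 over all T cells; its main interval, -0.01 to 0.74, held 0. The macrophage interferon median was 0.40 (stricter filter), 0.20 (no filter), 0.16 (no filter, doublets kept), 0.19 (doublets kept), 0.23 (resolution 2), 0.45 (mean over cells) and 0.42 (immune cells alone), and clustering the libraries alone gave no value. Apart from the mean over cells, each value comes from a clustering in which dendritic cells had a class of their own. MHC class I and interferon medians in epithelial cells stayed above 0 in every alternative run, as did the macrophage interferon median wherever a value could be had. Of the genes named by size, 24 in each of the epithelial, T cell, macrophage and neutrophil classes and 10 in each other class, all were past 1.5-fold with size factors, and with doublets kept 22, 23, 22, 24 and 10 were. Size factors shift all genes of a class alike and these genes were picked by size, so the size-factor result was largely fixed in advance. Of the 4 simulated classes, depth limits T cells and macrophages most, since at 1.5-fold their simulated intervals were on the right side of 1 for 68% and 64% of changed genes. The CD8 sub-clusters, with 180909 control and 136178 JQ1 UMIs, were not simulated. Nor were the CD8-gated cells, 24 in control and 40 in JQ1, with 79364 and 158082 UMIs.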

Other observations

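Clustering immune cells alone and values within single epithelial clusters were chosen after the data were seen. Dendritic-like cells, found when immune cells were clustered alone, carried more T-cell and monocyte chemokines under JQ1. Of 9 measured members 6 were higher and 1 lower by at least 1.5-fold, with a median log2 ratio of 0.91 (0.76 to 1.18). Il1a, an alarm cytokine, had 4.01 CPM in control and 123 CPM in JQ1, and Cd207, the Langerhans cell lectin, was 76.0-fold lower. The MHC class II median of dendritic-like cells was -0.19 (-0.28 to -0.05). Of their 97 control cells 21 lay in the Cd207 cluster, which held 0 JQ1 cells, so these values may come in part from that cluster. Both this class and the gamma-delta or Th17-type sub-cluster, with 60 control cells, were under the limit of 100 cells for naming genes. In the gamma-delta or Th17-type T sub-cluster Il17f was 2.37-fold and Il22 3.50-fold lower. 

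In the Krt13 cluster of epithelial cells squamous differentiation genes had a median of -0.38 (-0.45 to -0.34) with 6 of 15 members lower, and the partial EMT list had a median of 0.57 (0.44 to 0.74). Free RNA from other cells was not tested as a source of these values. In the Krt15 and Krt6b clusters the squamous differentiation medians were 0.14 and -0.02 and the partial EMT medians -0.02 and 0.04, against 0.06 and -0.09 over all epithelial cells. The difference between clusters was not tested, and a median alone does not show how many members were lower. The JQ1 erythroid-like cells carried the proliferation marker Mki67 at 249 CPM, and the JQ1 cells of the Elane cluster at 113 CPM. Xist, of the inactive X chromosome, had 485 CPM in control and 644 CPM in JQ1, and the Y-linked gene Ddx3y 13.2 and 28.9 CPM. Haemoglobin RNA reached 9515 CPM in JQ1 and 1.20 CPM in control macrophage or monocyte-like cells.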
